A study of Homo sapiens with 6 samples.

How the data were processed

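Gene expression was measured in OCUBM cells, a human cell line given in the labels as mammary, on 6 Affymetrix HG-U133_Plus_2 arrays, 1 array per sample. The labels place the arrays in 3 groups of 2: cells given the transfection reagent Lipofectamine without a vector (control), cells transfected with IGF1R, the insulin-like growth factor 1 receptor, and cells given the reagent together with lipopolysaccharide (LPS), a component of the outer membrane of Gram-negative bacteria. The dose of LPS, the time between treatment and harvest and the vector are not given in the sources used here. The labels call the samples biological replicates but do not say whether they came from separate cultures on separate days, so the p-values measure only the spread between these samples.

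Per the labels' protocols, total RNA was extracted with a column kit and biotin-labelled cRNA was prepared from it by the manufacturer's standard procedure. The deposited values are the authors' probe set intensity (signal) values on a linear scale, made with GCOS, the array manufacturer's software, per the submitters' processing notes. Its version, the background steps and any scaling target are not given in the sources used here. Per the file headers of the instrument records, all 6 arrays were of the same chip type, the replicate number equalled the fluidics run, and each group had its own fluidics module. Module and group could therefore not be told apart, while each run held 1 array of every group.

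The 2%-trimmed mean of the deposited signals lay between 55.1 and 94.9 over the 6 arrays, a 1.72-fold range, so the values were not at a common level. Under the rule fixed before the data were examined (scaling wherever these means differed by over 5%), every array was scaled to one trimmed mean. The pseudocount was 1, the 10th percentile of the deposited signals, and 18 values were exactly 0. All fold changes are differences of mean log2(scaled signal + 1) and understate changes of dim probe sets. Probe sets whose mean over the 6 arrays was at or above the median were kept, which was a log2 value of 3.39. This left 27307 of the 54613 probe sets that are not manufacturer's controls, and the other 62 probe sets on the array were used only to describe RNA quality and labelling. The number of arrays limits the precision of every value.

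Gene names came from the platform annotation. Of the probe sets, 41091 had 1 gene symbol, 1801 had several and 11721 had none listed here. No gene was named from a probe set with several. Entrez identifiers of 41043 were found in a RefSeq gene table of assembly GRCh38.p14, which changed 0 symbols. Because the arrays name no genome build, no coordinates are given. A gene was represented by its brightest probe set, which gave 12677 genes.

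Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend) over all 6 arrays, which left 3 residual degrees of freedom, since 2 arrays against 2 leave fewer. The tests were two-sided, and p-values were adjusted by Benjamini-Hochberg over all 27307 probe sets with a threshold of 0.05. An exact permutation test of 2 arrays against 2 cannot go below p = 0.33, so all calls rest on the spread that limma pools over probe sets. On simulated data with known changes in 200 of the 27307 probe sets, the test of IGF1R against control called 48% of changes of log2 size 1 and 84% of those of size 2, with 12 false calls among 144. The test of LPS against control called 43% and 83%, with 14 false calls among 140. The simulated noise was normal with the same spread in all groups, although the LPS replicates lay closer together than the others. These rates may therefore not hold for the real comparisons.

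Before the data were examined, 25 gene lists were fixed. They cover the IGF axis, immediate-early and MAPK feedback genes, FOXO targets, S phase and DNA replication, G2 and mitosis, interferon-stimulated genes, antigen presentation, NF-kB and inflammatory genes, the LPS receptor pathway, the unfolded protein and integrated stress response, heat shock, sterol synthesis, fatty acid synthesis, glycolysis and hypoxia, p53 targets, oestrogen response, epithelial and mesenchymal genes, cytosolic ribosomal proteins, mitochondrial respiration, rRNA processing and MYC targets, apoptosis regulators, replication-dependent histones, leukocyte markers, and fibroblast and endothelial markers. Lists with at least 5 measured members (23 lists) were tested with limma's camera at its preset inter-gene correlation of 0.01, which compares a list's genes with all others, with Benjamini-Hochberg adjustment over the lists. An estimated correlation and fry, a rotation test of each list by itself, were alternatives. For some lists the estimate lay below the preset 0.01, so a higher p with it does not always come from inter-gene correlation. Some genes stood in more than 1 list.

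The genes named were fixed by rule before the data were examined. For IGF1R against control and for LPS against control they are the 12 largest rises and the 12 largest falls among genes past the threshold whose arrays did not overlap between groups. Where fewer passed in a direction, genes with the smallest p were added up to 6 and are said not to pass. For IGF1R against LPS, 6 were taken per direction. Beside these, the rule takes every IGF1R probe set, TLR4, LY96 and CD14, and up to 4 members of a list that passed, or up to 2 that did not. Genes named outside the rule are said to be chosen after their values were seen.

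The alternatives were another pseudocount or a floor, quantile normalization or median centring, no filter or a stricter one, eBayes without the trend or robust, only the 2 groups compared, the replicate number (which is also the fluidics run) as a block, leaving out each array in turn, averaging a gene's probe sets, leaving out probe sets that may cross-hybridise (names ending in _x_at or _s_at), a fold rule in place of the test, and a minimum fold. Further alternatives were chosen after seeing the data: the ACTB 3'/5' signal ratio as a covariate, leaving out both arrays with the highest such ratio, and scaling each array on the poly-A control probe sets, which detect bacterial transcripts that can be added to the RNA before labelling.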

Results

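The series measured gene expression in OCUBM cells after transfection with IGF1R or exposure to LPS, each against cells given only the transfection reagent, with 2 arrays per group. The 2 replicates of a group correlated across probe sets at r = 0.969 in the control, 0.966 in the IGF1R-labelled and 0.985 in the LPS arrays. The median absolute log2 difference between replicates was 0.24, 0.27 and 0.12 in the same order, so the LPS replicates lay closest together. At most 1.34% of values were identical between replicates, and no array was counted as a duplicate.

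The arrays differed in signs of RNA quality and labelling. The ACTB 3'/5' signal ratio, which rises when transcripts are degraded or labelled short, was 8.57 and 4.74 in the control arrays, 7.25 and 4.15 in the IGF1R-labelled arrays, and 2.54 and 2.52 in the LPS arrays. The GAPDH 3'/5' ratio was 1.28 ± 0.0837 (SD, n = 2) in control, 1.67 ± 0.0195 in IGF1R-labelled and 1.12 ± 0.0120 in LPS arrays. The poly-A control probe sets had a geometric mean scaled signal of 68.0 ± 19.6 in control, 166 ± 4.81 in IGF1R-labelled and 52.0 ± 2.09 in LPS arrays, and all 24 of them were higher in both IGF1R-labelled arrays than in both controls.

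**Figure D1:**
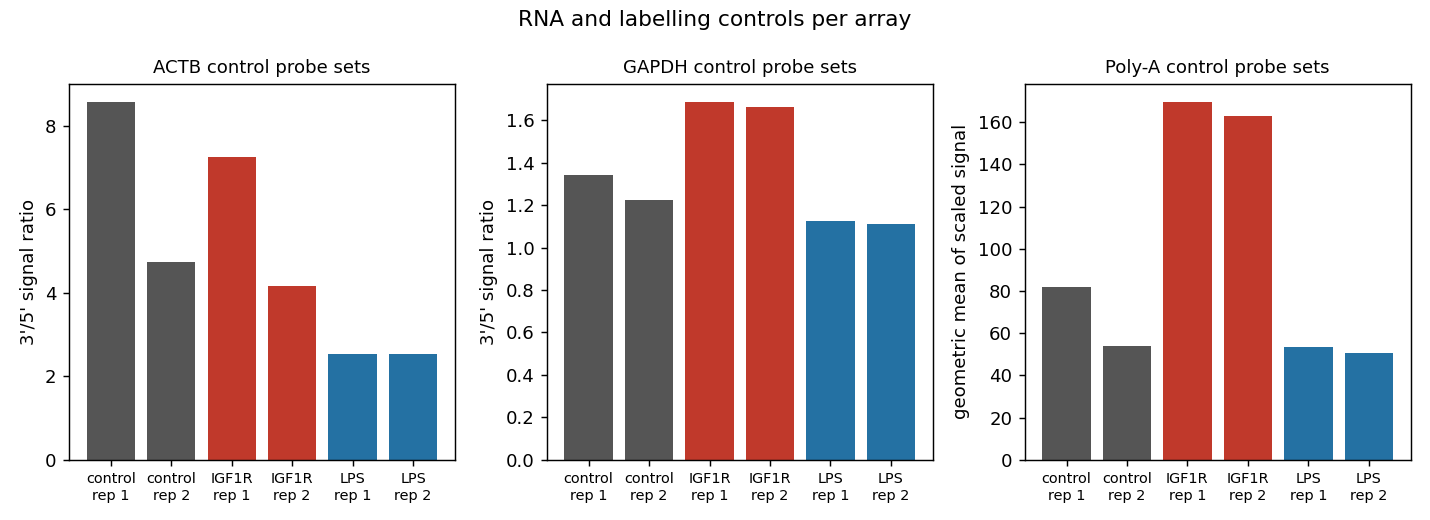
RNA and labelling controls of each array. Bars give the ACTB and GAPDH 3'/5' signal ratios and the geometric mean of the scaled poly-A control signals for the 6 arrays, coloured by group, 1 bar per array. The LPS arrays had the lowest ACTB ratios (2.54 and 2.52) and the IGF1R-labelled arrays the highest poly-A signals (170 and 163).

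IGF1R itself did not pass the test in the arrays labelled as transfected with it. Probe set 203627_at had a scaled signal of 60.4 ± 1.94 (SD, n = 2) in control and 65.5 ± 8.11 in IGF1R-labelled arrays, a log2 fold change of 0.11 with a 95% interval from -0.38 to 0.60 (limma, adjusted p = 0.862). Probe set 203628_at gave a log2 fold change of 0.41 (interval -0.19 to 1.02, adjusted p = 0.523), from 37.3 ± 7.20 to 49.9 ± 8.69. Probe set 225330_at gave 0.21 (interval -0.34 to 0.76, adjusted p = 0.737), from 43.3 ± 4.03 to 50.7 ± 10.6. The other IGF1R probe sets lay below the filter. Of these, 208441_at read 4.8 and 0.5 in the control arrays, 8.5 and 9.5 in the IGF1R-labelled arrays and 5.0 and 3.6 in the LPS arrays, and 243358_at read 4.9 and 1.0, 0.9 and 3.7, and 1.4 and 6.6. Whether any of these probes lies in the part of the transcript that the vector carried is not known here, so the group is called IGF1R-labelled throughout.

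**Figure D2:**
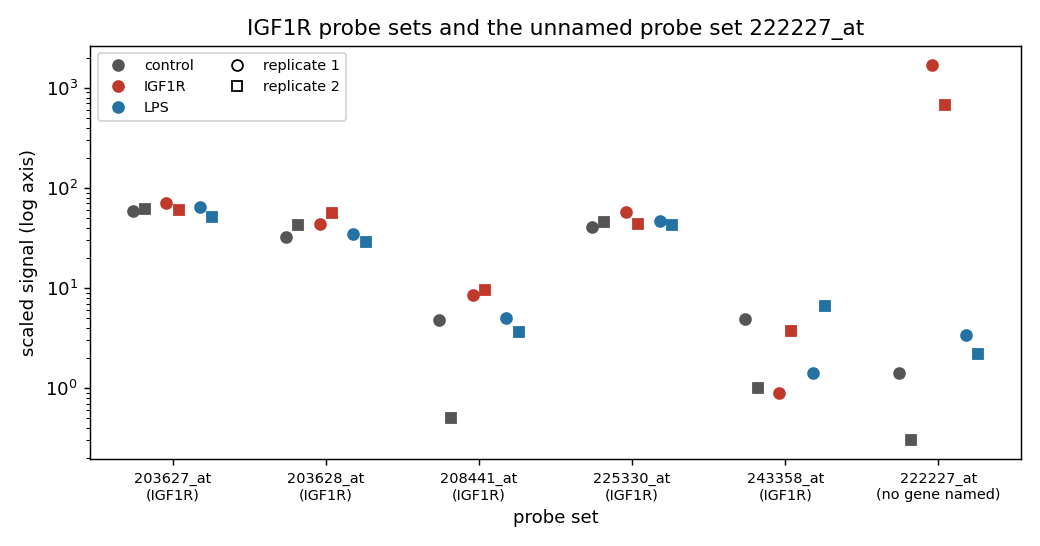
Scaled signal (log axis) of the 5 IGF1R probe sets and of the unnamed probe set 222227_at in each of the 6 arrays; colour marks the group and shape the replicate. The IGF1R probe sets past the filter overlap or lie close between groups, as for 203627_at (60.4 in control, 65.5 in IGF1R-labelled arrays on average), while 222227_at reads 1703.9 and 680.5 in the IGF1R-labelled arrays and at most 3.4 elsewhere.

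IGF1R-labelled against control arrays asked which genes differed after transfection with the receptor. As lists, immediate-early and MAPK feedback genes were higher and interferon-stimulated genes lower in camera, with an adjusted p = 0.203 and an adjusted p = 0.0911 with an estimated correlation, and 6 of 25 and 6 of 36 members passed. The transcription factor gene EGR1 rose 3.60-fold, from 264 ± 59.0 to 942 ± 41.0 (SD, n = 2), and the chemokine gene CCL20 rose 5.06-fold, from 316 ± 105 to 1558 ± 89.7. The chemokine gene CXCL11, an interferon target, fell by 1.33 on the log2 scale, from 571 ± 17.7 to 226 ± 0.0466, and the kallikrein protease gene KLK7 fell by 3.10, from 30.2 ± 3.59 to 2.64 ± 0.262. In all, 154 of 12677 genes changed at an adjusted p under 0.05 in limma, 92 up and 62 down. Over all 27307 probe sets, on which the adjustment was made, 296 were higher and 101 lower, a more uneven split.

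Among the 12 largest rises were MPHOSPH8 (log2 fold change 3.71), LMO7 (3.63), the circadian repressor gene CRY2 (3.53), the MAPK inhibitor gene SPRY4 (3.38), FAM111B (2.97), STAG3L3 (2.43), SECISBP2 (2.38), CCL20 (2.34), ANKRD36B (2.22), NKTR (2.16), NBL1 (2.16) and PPP1R15A (2.15), which encodes a phosphatase subunit of the integrated stress response. LMO7, CRY2, SPRY4, STAG3L3, ANKRD36B and NBL1 had mean scaled signals from 1.74 to 7.91 in control, below the filter level of 9.49, so their folds were measured from near the floor. FAM111B was at 12.7 ± 12.5 (SD, n = 2) in control, and its log2 fold change was 4.14 in run 1 and 1.79 in run 2. The other 2 measured probe sets of MPHOSPH8 and the other probe set of SECISBP2 had fold changes of the opposite sign, as had 1 of the other 2 of NKTR. The 12 largest falls were KLK7 (-3.10), NAV3 (-2.10), RTP4 (-1.68), SP140L (-1.67), GIMAP2 (-1.66), the aquaporin gene AQP3 (-1.63), CLEC7A (-1.59), the protease inhibitor gene PI3 (-1.58), the complement factor gene CFB (-1.57), PLAAT2 (-1.56), APOL1 (-1.48) and BBOX1 (-1.36). The other probe set of PLAAT2 had a fold change of the opposite sign. Mean scaled signals of KLK7 and NAV3 in the IGF1R-labelled arrays, 2.64 and 6.43, lay below the filter level. Of the 24 genes, 18 kept their call when only the arrays of both groups were fitted.

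**Figure D3:**
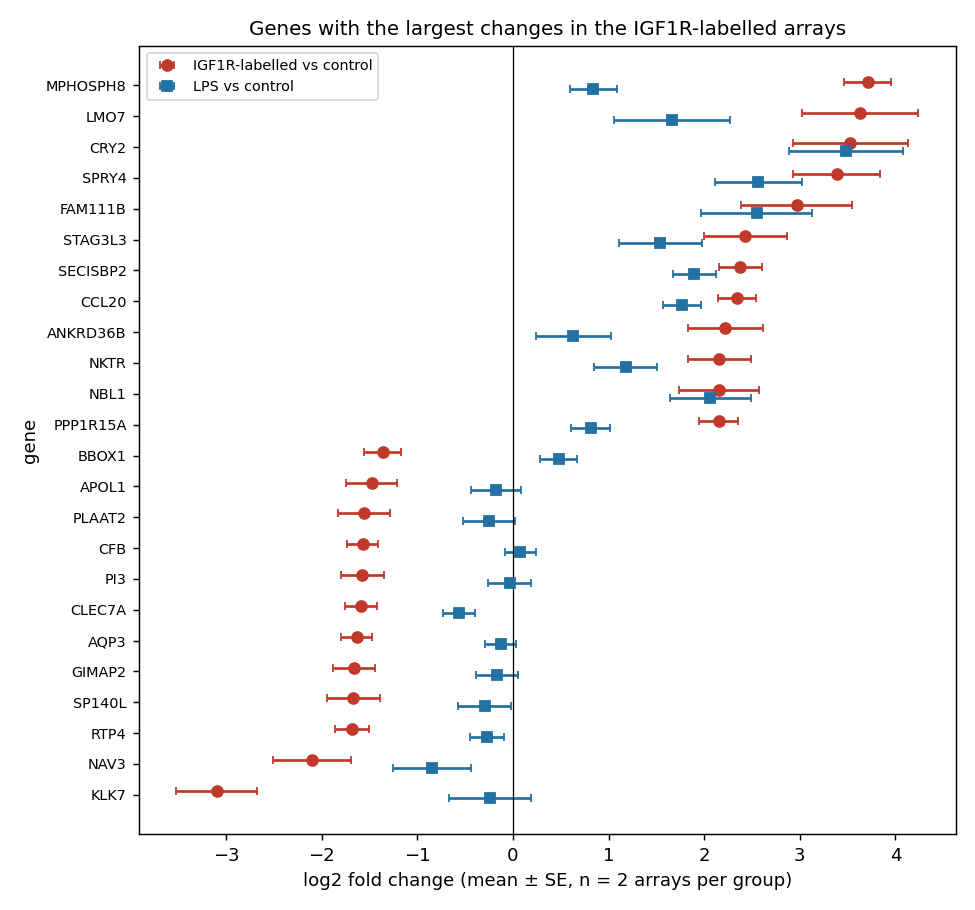
Log2 fold change against control (mean ± SE from limma, n = 2 arrays per group) of the 24 genes with the largest changes in the IGF1R-labelled arrays, for IGF1R-labelled arrays (circles) and LPS arrays (squares). MPHOSPH8 stands at 3.71 and KLK7 at -3.10 in the IGF1R-labelled arrays; of the 24 genes, SECISBP2 and CCL20 passed the test in the LPS arrays too.

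Of 25 measured immediate-early and MAPK feedback genes, 6 rose, 0 fell and 19 did not pass, with 16 rising when adjusted over the list alone. SPRY4, EGR1 (1.85), the stress-induced factor gene ATF3 (1.41) and the ERK phosphatase gene DUSP6 (1.33) had the largest changes among those that rose. The list was higher than other genes (camera, adjusted p = 7.72e-14), with an adjusted p = 0.203 with an estimated correlation, and its call held without any single array. Of 36 interferon-stimulated genes, 6 fell, 0 rose and 30 did not pass, and 19 fell and 1 rose when adjusted over the list alone. CXCL11, MX2 (-1.09), IFI35 (-0.94) and the antiviral synthetase gene OAS2 (-0.75) had the largest changes among those that fell. The list was lower (camera, adjusted p = 4.21e-11), with an adjusted p = 0.0911 with an estimated correlation, and its call also held without any single array. The estimated correlation was 0.1 for the immediate-early and -0.0103 for the interferon-stimulated list. The latter lay below the preset 0.01, so inter-gene correlation does not account for that list's higher p. Both lists passed by fry (adjusted p = 0.0161 and 0.00272). In both fluidics runs the list medians kept their side, at 0.80 and 0.51 for immediate-early and MAPK feedback genes and at -0.31 and -0.35 for interferon-stimulated genes.

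Of 13 antigen presentation genes, 3 fell and 10 did not pass, with 6 falling when adjusted over the list alone. The regulator gene of MHC class I NLRC5 (-1.14), the immunoproteasome subunit gene PSMB9 (-1.13) and the peptide transporter gene TAP2 (-0.90) fell. Of the 13 genes, 6 lay above 0 and 7 below, with a median log2 fold change of -0.02 and a mean of -0.31. Their estimated correlation was -0.0753, and the list passed by fry, as lower (adjusted p = 0.0144). The list was lower (camera, adjusted p = 0.0141), with an adjusted p = 0.338 with an estimated correlation, and the call ended without control replicate 2 (adjusted p = 0.162) or IGF1R replicate 2 (0.0626). Of 26 NF-kB and inflammatory genes, 5 rose, 1 fell and 20 did not pass, with 9 rising and 4 falling when adjusted over the list alone. CCL20, CXCL3 (2.12), which encodes a neutrophil chemokine, and the cytokine gene TNF (1.45) rose and CFB fell. The list was higher (camera, adjusted p = 0.0351), with an adjusted p = 0.338 with an estimated correlation. Its call ended without control replicate 2 (adjusted p = 0.228) or IGF1R replicate 2 (0.12), with no filter (0.0816), with the filter at the 75th percentile (0.0748), with averaged probe sets (0.141), without probe sets that may cross-hybridise (0.612) or with the ACTB 3'/5' ratio as a covariate (0.0618). Its median was -0.08 in run 1 and 0.30 in run 2.

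Of 26 genes of the unfolded protein and integrated stress response, 3 rose and 23 did not pass, with 5 rising when adjusted over the list alone. PPP1R15A, the transcription factor gene DDIT3 (0.99) and the chaperone gene HSP90B1 (0.87) rose. The list was higher (camera, adjusted p = 0.0126), with an adjusted p = 0.338 with an estimated correlation, and the call ended without control replicate 1 (adjusted p = 0.109), IGF1R replicate 1 (0.126) or both (0.302). Of 8 replication-dependent histone genes, 2 rose over all genes and 2 when adjusted over the list alone, H2BC4 (1.31) and H2BC21 (1.21). That list was higher (camera, adjusted p = 0.0452; adjusted p = 0.338 with an estimated correlation), but not without control replicate 1 (0.159), IGF1R replicate 1 (0.204) or both (0.415). Centring on the array median (0.0505), no filter (0.0525) and averaged probe sets (0.0642) ended that call too. Of 19 FOXO targets, the growth arrest gene GADD45A (0.84) rose, and 5 rose and 2 fell when adjusted over the list alone. The list was higher (camera, adjusted p = 0.0452; adjusted p = 0.589 with an estimated correlation), but not without control replicate 1 (0.298), IGF1R replicate 1 (0.507) or both (0.757). No filter (0.148), the filter at the 75th percentile (0.168), averaged probe sets (0.0721) and the ACTB 3'/5' ratio as a covariate (0.0521) ended it too.

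None of 27 S phase and DNA replication genes passed (0 over all genes and 0 adjusted over the list alone), while 24 lay above 0, with a median log2 fold change of 0.22. E2F1 (0.75, adjusted p = 0.117) and CHAF1A (0.47, adjusted p = 0.240) had the largest absolute values, and 1 of the other 2 probe sets of CHAF1A had the opposite sign. The list was higher (camera, adjusted p = 5.23e-05), with an adjusted p = 0.338 with an estimated correlation, and the call ended without control replicate 2 (adjusted p = 0.0719).

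Of 10 fatty acid synthesis genes, the desaturase gene SCD fell (-0.95) and 9 did not pass, with 2 falling when adjusted over the list alone. The list was lower (camera, adjusted p = 0.0126; adjusted p = 0.338 with an estimated correlation), but not without control replicate 2 (0.116), with averaged probe sets (0.146) or without probe sets that may cross-hybridise (0.548). Of 15 sterol synthesis genes, 0 passed over all genes and 4 fell when adjusted over the list alone. HMGCS1, which encodes an enzyme of the mevalonate pathway, had a log2 fold change of -0.89 (adjusted p = 0.116) and STARD4 of -0.77 (adjusted p = 0.0987). That list was lower (camera, adjusted p = 0.00318; adjusted p = 0.338 with an estimated correlation), but not without control replicate 1 (0.157) or without both control replicate 1 and IGF1R replicate 1 (0.238). Of 23 glycolysis and hypoxia genes, 0 passed over all genes or adjusted over the list alone, with NDRG1 at -1.26 (adjusted p = 0.532) and ANKRD37 at -0.85 (adjusted p = 0.505). The list was lower (camera, adjusted p = 0.00816; adjusted p = 0.724 with an estimated correlation). Its direction turned without control replicate 2 (adjusted p = 0.158), its call ended without IGF1R replicate 1 (0.0512), without IGF1R replicate 2 (0.0626) or without probe sets that may cross-hybridise (0.119), and its median was 0.18 in run 1 and -0.81 in run 2.

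The remaining lists were not shifted in camera, although some members passed. Of 20 p53 targets, GDF15 (1.59), PMAIP1 (1.46) and GADD45A rose, and 4 rose and 2 fell when adjusted over the list alone (adjusted p = 0.534 for the list). PMAIP1 was also the 1 of 19 apoptosis regulators that rose (list, adjusted p = 0.756; 1 adjusted over the list alone). NRIP1 (1.30) rose among 14 oestrogen response genes (list, adjusted p = 0.534; 2 adjusted over the list alone), where the median of -0.11 and the mean of 0.13 differed in sign. LYAR (0.95) rose among 20 rRNA processing and MYC target genes (list, adjusted p = 0.122; 2 adjusted over the list alone). No member passed over all genes in the IGF axis (list, adjusted p = 0.534), G2 and mitosis (0.122), the LPS receptor pathway (0.626), heat shock (0.979, median 0.01 and mean -0.04), epithelial (0.586), mesenchymal (0.615), cytosolic ribosomal protein (0.14) or mitochondrial respiration (0.168) lists. Adjusted over the list alone, 1 LPS receptor pathway gene and 1 heat shock gene fell and 0 passed in the other 6 lists. Too few leukocyte markers (3) and fibroblast and endothelial markers (4) were measured to test those lists, and 0 of these markers passed in any comparison.

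At an unadjusted p under 0.05 there were 1830 genes. The main fit pools the spread of all 3 groups, and the LPS replicates lay closest together. Its calls may therefore rest on too small a spread for the control and IGF1R-labelled arrays. The count of 154 fell to 78 with only both groups in the fit, to 2 without the intensity trend, to 98 with a gene's probe sets averaged and to 100 without probe sets that may cross-hybridise. Leaving out arrays, it was 64 without control replicate 1, 58 without IGF1R replicate 1, 67 without LPS replicate 1 and 65 without LPS replicate 2. Centring on the array median turned the split of 92 up and 62 down into 68 and 82, and scaling on the poly-A controls shifted all genes by -1.31 on the log2 scale and gave 12 up and 10707 down, so directions are relative to the trimmed mean.

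LPS against control arrays asked which genes responded to LPS in the presence of the transfection reagent. CCL20 rose 3.39-fold, from 316 ± 105 to 1043 ± 9.93 (SD, n = 2), and SECISBP2 rose 3.72-fold, from 62.7 ± 20.5 to 231 ± 28.0 (limma, adjusted p = 0.0452 for both). These were the only 2 of 12677 genes past the threshold, with 0 falling and 1558 at an unadjusted p under 0.05. Over all 27307 probe sets, 10 were higher and 1 lower. Of these 11, 7 belonged to genes whose representing probe set did not pass, 1 had no gene listed and 1 had several. The last, 200888_s_at, had the smallest adjusted p (0.00117), with a log2 fold change of 1.85. The largest log2 fold change of the 11 was that of an NFKBIZ probe set (2.51, limma, adjusted p = 0.0452). It was not the one representing the gene, and it was chosen after its value was seen. The other probe set of SECISBP2 had the same sign without passing.

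Further genes had small p without passing. STT3A (log2 fold change 1.18, adjusted p = 0.0559), HSP90B1 (1.10, 0.0665), ABHD3 (0.71, 0.0845) and KRABD5 (1.23, 0.0895) were higher. The other probe set of HSP90B1 had the opposite sign. The transcription factor gene SOX9 (-0.98, adjusted p = 0.0665), MUCL1 (-0.58, 0.0909), the proteasome activator gene PSME1 (-0.69, 0.0949), RPL41 (-0.50, 0.0949), CD24 (-0.52, 0.0950) and REEP1 (-0.91, 0.0995) were lower. Scale factors averaged 1.18 in control and 0.751 in LPS arrays. Before scaling, the bright genes MUCL1, RPL41 and CD24 were not lower in the LPS arrays, so their falls rest on the scaling. With the fluidics run, which held 1 array of every group, as a block, 6 of these 10 genes passed and the count of 2 genes became 47. The receptor genes TLR4 and CD14 lay below the filter in all their probe sets. LY96, which encodes the co-receptor of TLR4, was at 14.5 ± 7.08 in control and 19.3 ± 2.35 in LPS arrays (log2 fold change 0.46, adjusted p = 0.775).

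Of 26 NF-kB and inflammatory genes, CCL20 rose and 25 did not pass, with 5 rising when adjusted over the list alone. Each gene was counted by its brightest probe set, so the NFKBIZ probe set that rose was not counted. The list was higher (camera, adjusted p = 0.000129), with an adjusted p = 0.654 with an estimated correlation, and its call held without any single array but ended without probe sets that may cross-hybridise (adjusted p = 0.0897). Of 25 immediate-early and MAPK feedback genes, 0 passed and 3 rose when adjusted over the list alone, with SPRY4 at 2.57 (adjusted p = 0.0921) and ETV5 at -1.04 (adjusted p = 0.299). That list was higher (camera, adjusted p = 0.0372; adjusted p = 0.654 with an estimated correlation), but not without control replicate 1 (0.186), LPS replicate 1 (0.0859) or both control replicate 1 and IGF1R replicate 1 (0.221). Averaged probe sets (0.0568) and leaving out probe sets that may cross-hybridise (0.239) ended that call, and its median was 0.26 in run 1 and -0.02 in run 2. Of 23 cytosolic ribosomal protein genes, 0 passed and 6 fell when adjusted over the list alone, with RPL22 at -0.47 (adjusted p = 0.117) and RPS23 at -0.44 (adjusted p = 0.121). The other probe set of RPS23 and 1 of the other 4 of RPL22 had the opposite sign. Before scaling, RPL22 and RPS23 were not lower in the LPS arrays either. The list was lower (camera, adjusted p = 0.000129; adjusted p = 0.654 with an estimated correlation), and with quantile normalization it was on the other side (adjusted p = 0.675). Its adjusted p was 0.322 without probe sets that may cross-hybridise and 0.792 with the ACTB 3'/5' ratio as a covariate, an alternative chosen after seeing the data. The LPS arrays also had the lowest ACTB 3'/5' ratios, close together and apart from all other arrays. In comparisons with LPS this covariate can therefore hardly be told apart from the group, and a call that it ends decides nothing about the cause.

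The other 20 tested lists were not shifted, the smallest adjusted p being that of the interferon-stimulated list (0.0669, lower, 2 rising and 5 falling when adjusted over the list alone). Sterol synthesis and glycolysis and hypoxia genes followed (0.0744 each, higher), with 0 members past the threshold when adjusted over each list alone. With the fluidics run as a block, the glycolysis and hypoxia list passed (camera, adjusted p = 0.0322). Its median was 0.60 in run 1 and -0.30 in run 2. The test's direction was higher for the IGF axis, where the median was -0.05 and the mean -0.01, and for the stress response and p53 target lists, where the medians were -0.04 and -0.05 and the means 0.06 and 0.05. The count of genes was 0 with only both groups in the fit, without the intensity trend or with quantile normalization, and no list passed without probe sets that may cross-hybridise. It was 42 without control replicate 2, 1 without control replicate 1, and 0 without any other single array.

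IGF1R-labelled against LPS arrays tested the difference between the treatments. In limma, 177 genes differed, 87 up and 90 down in the IGF1R-labelled arrays, and over all 27307 probe sets 200 were higher and 166 lower. MPHOSPH8 was 7.32-fold higher and BBOX1 3.58-fold lower in the IGF1R-labelled arrays. Of the other 2 probe sets of MPHOSPH8, 1 had the same sign, without passing. The chemokine genes CCL8 and CCL4 were lower at 30.1 ± 14.4 against 145 ± 17.7 and at 38.0 ± 0.888 against 143 ± 0.564 (SD, n = 2).

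The 6 largest positive differences were CD5 (log2 fold change 3.12), MUC8 (3.09), MPHOSPH8 (2.87), ANKRD20A11P (2.79), GARIN4 (2.41) and LIMS2 (2.21), of which all but MPHOSPH8 had mean scaled signals from 3.05 to 5.37 in the LPS arrays, below the filter level of 9.49. The 6 largest negative ones were KLK7 (-2.86), CCL8 (-2.30), CCL4 (-1.88), BBOX1 (-1.84), HIRA (-1.83) and CXCL11 (-1.70).

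Of 25 immediate-early and MAPK feedback genes, 4 were higher, EGR1 (1.61), DUSP6 (1.49), ATF3 (1.38) and DUSP4 (0.90), and 11 were higher when adjusted over the list alone (camera, adjusted p = 9.35e-07; adjusted p = 0.341 with an estimated correlation). Of 36 interferon-stimulated genes, 7 were lower, among them CXCL11, IFI35 (-1.05), MX2 (-0.93) and PARP14 (-0.91), and 1 was higher, with 11 lower and 1 higher when adjusted over the list alone (camera, adjusted p = 8.02e-05; adjusted p = 0.341 with an estimated correlation). INSIG1 (-1.10) and FDPS (-0.67) were lower among 15 sterol synthesis genes, and SREBF1 (-1.31) and SCD (-1.27) among 10 fatty acid synthesis genes, with 5 and 4 lower when adjusted over each list alone. The other probe set of SREBF1 had the opposite sign. Both lists were lower (camera, adjusted p = 5.63e-06 and 0.000229; adjusted p = 0.341 with an estimated correlation for each). RPL3 (0.70) and RPL10A (0.51) were higher among 23 cytosolic ribosomal protein genes, with 11 higher and 1 lower when adjusted over the list alone (camera, adjusted p = 3.71e-06; adjusted p = 0.341 with an estimated correlation). That call ended with quantile normalization (adjusted p = 0.691), without probe sets that may cross-hybridise (0.163) and with the ACTB 3'/5' ratio as a covariate (0.0531). S phase and DNA replication genes were higher as a list (camera, adjusted p = 0.000164; adjusted p = 0.341 with an estimated correlation), with 0 passing over all genes and 7 higher when adjusted over the list alone. E2F1 (0.70, adjusted p = 0.120) and RRM2 (0.70, adjusted p = 0.0610) had the largest absolute values in it, and the list's call ended with the ACTB 3'/5' ratio as a covariate (adjusted p = 0.249). RRM2 passed with the fluidics run as a block (limma, adjusted p = 0.0487). Glycolysis and hypoxia genes were lower as a list (camera, adjusted p = 2.18e-05; adjusted p = 0.437 with an estimated correlation), with 0 passing over all genes and 2 lower when adjusted over the list alone, and turned with the ACTB 3'/5' ratio as a covariate (adjusted p = 0.849). These 7 lists kept their call without any single array. Because the ACTB ratio set the LPS arrays apart from all others, losses with that covariate cannot tell RNA quality or labelling from treatment.

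The call of 4 further lists ended without at least 1 array, and with the ACTB 3'/5' ratio as a covariate (adjusted p = 0.249 for FOXO targets and for rRNA processing and MYC targets, 0.568 for epithelial and 0.801 for mitochondrial respiration genes). That covariate largely follows the LPS group, so its part in these losses cannot be told apart from treatment. FOXO targets were higher (camera, adjusted p = 0.038; adjusted p = 0.437 with an estimated correlation), with the insulin receptor gene INSR (1.34) passing (1 higher when adjusted over the list alone), but not without IGF1R replicate 1 (0.396) or LPS replicate 2 (0.0623). No filter (0.117), the filter at the 75th percentile (0.249), averaged probe sets (0.113), leaving out probe sets that may cross-hybridise (0.0996) and leaving out control replicate 1 and IGF1R replicate 1 together (0.363) ended it too. rRNA processing and MYC targets were higher (camera, adjusted p = 0.0332; adjusted p = 0.341 with an estimated correlation), with 0 passing over all genes and 2 when adjusted over the list alone, but not without IGF1R replicate 2 (0.165) or LPS replicate 1 (0.0596), with no filter (0.0696) or without probe sets that may cross-hybridise (0.111). Epithelial genes were lower (camera, adjusted p = 0.037; adjusted p = 0.341 with an estimated correlation), although CD24 was higher (0.58), with 1 higher and 3 lower when adjusted over the list alone. The call did not hold without IGF1R replicate 1 (0.0935), IGF1R replicate 2 (0.0634) or LPS replicate 2 (0.0641), with the filter at the 75th percentile (0.133) or without probe sets that may cross-hybridise (0.0996). Mitochondrial respiration genes were lower (camera, adjusted p = 0.032; adjusted p = 0.353 with an estimated correlation), with 0 passing over all genes or adjusted over the list alone, but not without IGF1R replicate 1 (0.23), LPS replicate 2 (0.0623) or both control replicate 1 and IGF1R replicate 1 (0.199). The filter at the 75th percentile and leaving out probe sets that may cross-hybridise ended it too (0.111 each).

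Lists that did not shift held further genes past the threshold. PSMB9 (-0.88), NLRC5 (-0.85) and TAP2 (-0.81) were lower and 2 genes, among them HLA-C (0.48), were higher among antigen presentation genes (list, adjusted p = 0.126; 3 higher and 5 lower adjusted over the list alone). CFB (-1.65) was lower and CXCL8 (1.04) higher among NF-kB and inflammatory genes (list, adjusted p = 0.604; 5 higher and 6 lower adjusted over the list alone). PPP1R15A (1.34) was higher in the stress response list (0.0572), TWIST1 (1.36) in the mesenchymal list (0.328) and INSR in the IGF axis (0.922), while HSPB1 (-1.13) was lower among heat shock genes (0.586) and MDM2 (-0.92) among p53 targets (0.592). With the fluidics run as a block, the stress response list passed, as higher (camera, adjusted p = 0.0497). Of the 5 other probe sets of MDM2, 1 had the same sign, as had 1 of 2 for TAP2, 2 of 3 for HLA-C and 4 of 5 for CD24. Adjusted over each list alone, 4 stress response genes and 1 mesenchymal gene were higher, while the IGF axis and heat shock lists each had 1 higher and 1 lower, and p53 targets had 2 higher and 1 lower. The list of apoptosis regulators (adjusted p = 0.816) had a median of -0.04 and a mean of 0.01. The count of 177 genes was 1 without LPS replicate 2, 3 without LPS replicate 1, 41 without IGF1R replicate 1 and 383 without IGF1R replicate 2, and it was 0 without the intensity trend or with the ACTB 3'/5' ratio as a covariate, an alternative chosen after seeing the data. The ACTB ratio largely follows the LPS group, so the loss with that covariate cannot tell RNA quality or labelling from treatment. With the fluidics run as a block the count was 281. Centring on the array median turned the split of 87 up and 90 down into 61 and 104.

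**Figure D4:**
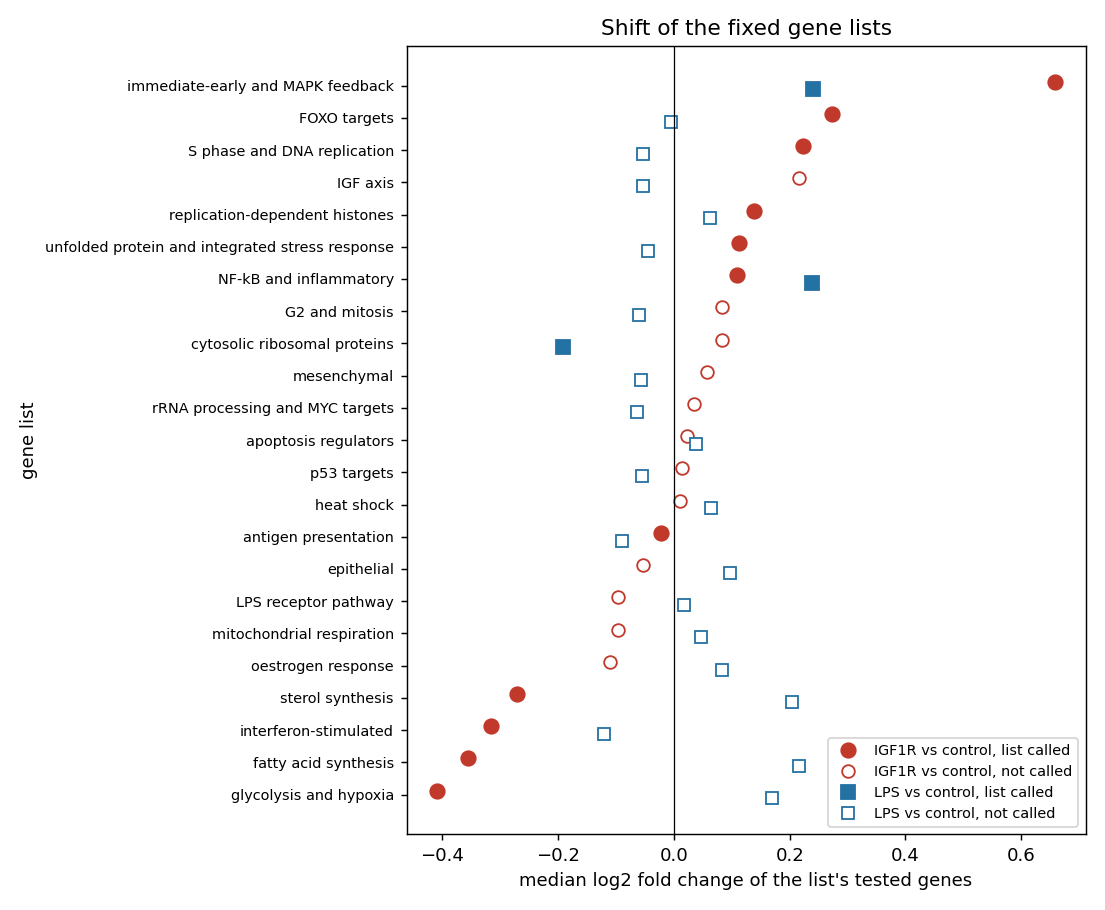
Median log2 fold change of the measured genes of each of the 23 tested lists, for IGF1R-labelled against control (circles) and LPS against control (squares); filled symbols are lists called by camera at an adjusted p under 0.05. Interferon-stimulated genes have a median of -0.32 and immediate-early and MAPK feedback genes of 0.66 in the IGF1R-labelled arrays.

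Both treatments were compared with the same control arrays. CCL20 and SECISBP2 rose in both comparisons. Across the 12677 genes, which are not independent replicates, the log2 fold changes against control correlated at r = 0.406, while 200 simulations of unchanged groups against the same controls gave r = 0.501 on average. The covariance was 0.0723 against a simulated 0.0462, a difference of 0.0261. The simulation gave all groups the same spread, although the control replicates lay further apart than the LPS replicates. It may thus understate the covariance that shared controls alone give. With a different control array for each treatment, r was 0.0964 one way and -0.0450 the other, with covariances of 0.0219 and -0.0118. The difference from the simulation therefore does not show a shared response.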

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

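The tests below on the GAPDH ratio, the scaling, the vector and probe set 222227_at were chosen only after the results were seen. The tests on the ACTB ratio and on RNA quality in the LPS arrays were also not planned and were added after the array measures were seen, but what each outcome would mean was written down before their own values were computed.

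Some signals outside the gene comparisons were higher in the IGF1R-labelled arrays than in both controls. The poly-A control probe sets had a geometric mean of 166.4, the middle 28S ribosomal RNA probe set a mean of 1276, and the unnamed probe set 222227_at a mean of 1192, all in scaled signal. The 28S probe set was also higher in the LPS arrays, at 624 against 271 in control. Of 4226 measured probe sets with no gene or several genes listed, 40 passed the limma threshold in IGF1R-labelled against control arrays (0.947%), a smaller share than the 1.45% over all probe sets, and 2 passed in LPS against control and 57 in IGF1R against LPS.

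The first pattern is the set of 154 genes called in the IGF1R-labelled arrays, among them EGR1, CCL20 and CXCL11. The ACTB 3'/5' ratio as a covariate left the median ratio of fold changes after to before at 0.999, with 151 of the 154 calls kept. That ratio overlapped between the groups (8.57 and 4.74 in control, 7.25 and 4.15 in IGF1R-labelled arrays). The covariate could therefore hardly move this contrast, and the kept calls add little. What argues against that trend as the whole cause is the overlap itself. The GAPDH 3'/5' ratio separated both groups by 0.307 on the log2 scale, so an effect of labelling length in that measure may be part of the changes and cannot be told apart from the treatment. Scaling on the poly-A controls left 42.4% of the 92 genes called higher above 0, but it moves nearly all genes alike, so this share follows from the size of the shift, and a global shift hidden by the trimmed mean stays open, since the labels do not say that equal amounts of these controls were added. With 0 groups given a vector without the receptor, effects of the vector DNA and of the receptor stay open as well.

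The second pattern is the rise of CCL20 and the group changes in the LPS arrays. These arrays had the lowest ACTB 3'/5' ratios, 2.54 and 2.52. Across genes, LPS minus control correlated at r = -0.107 (bootstrap SD 0.0124) with the difference between both IGF1R-labelled replicates, which also differ in the ACTB ratio. The bootstrap resampled genes, which are not independent. The value lay between the bounds set for and against an effect of RNA quality or labelling length, so that explanation and a response to LPS may both contribute. The 3'/5' ratio of dap, a poly-A control, averaged 8.41 ± 2.25 (SD, n = 2) in control, 5.97 ± 2.44 in IGF1R-labelled and 4.22 ± 0.665 in LPS arrays. Per array it was 10.0 and 6.82 in control, 7.70 and 4.25 in IGF1R-labelled, and 4.69 and 3.75 in LPS arrays. Like the ACTB ratio, it was higher in replicate 1 of every group. Because dap is not a transcript of the cells, labelling length may be part of the ACTB differences. Whether transcripts were degraded or labelled short was not tested.

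The third pattern is probe set 222227_at, which read 1703.9 and 680.5 in the IGF1R-labelled arrays. The lower of these was 203 times the highest of the other arrays, and both arrays carried it, which argues against a blemish on 1 array. It was the 1 probe set over 10 times higher in this way. A candidate explanation is a transcript made from the vector, which stays open because neither the vector nor the probe sequence is given in the sources used here. An induced endogenous transcript was not tested.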

How the results depend on the processing

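The settings that use the ACTB 3'/5' ratio or the poly-A controls, and the split of the control arrays, were chosen only after the data were seen. Of 2420 repeats of single-gene results, 1805 kept direction and side of the threshold, 508 lost the call, 66 gained one and 41 turned direction. Genes not called in the main fit are included and could not lose a call. For called genes, 699 repeats kept and 231 lost the call in IGF1R against control. These were 20 and 21 in LPS against control and 482 and 256 in IGF1R against LPS. Unless said otherwise, the cause was not tested. The counts of genes below can include genes not called in the main fit. In IGF1R against control, 116 genes differed at least 2-fold in all 4 pairs of arrays. Of these, 61 were among the 154 of the main fit. The main fit shared 70 of the 98 genes called with averaged probe sets and 87 of the 100 without _x_at and _s_at probe sets. Leaving out a control or IGF1R-labelled array also gave calls outside the main fit there. When an array is left out, its lone partner is assumed to vary like the other groups. List results under the eBayes settings say nothing, because camera uses its own trend. In comparisons with LPS the ACTB covariate can hardly be told apart from the group, because both LPS arrays lay below all others in that ratio. Low signal over background limits dim genes.

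For IGF1R against control, the count of 154 genes became 2 without the trend, 78 with only 2 groups, 98 with averaged probe sets, 100 without _x_at and _s_at probe sets, 58 to 112 when leaving out an array, 263 with the ACTB covariate, 2025 without both arrays of highest ACTB ratio (where the residual spread comes from the LPS arrays) and 10719 with poly-A scaling, which shifts all genes. The 11 lists became 7 without _x_at and _s_at probe sets, 6 to 11 when leaving out an array, 0 with an estimated correlation and 3 by fry.

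For LPS against control, the count of 2 genes became 0 with a floor, quantile normalization, no trend, only 2 groups, averaged probe sets or the ACTB covariate, 5 with the filter at the 75th percentile, 0 to 42 when leaving out an array, 1221 without both arrays of highest ACTB ratio, 76 with poly-A scaling, a shift of 0.36, and 70 by 2-fold in all 4 pairs. The 3 lists became 5 with no filter, 2 to 6 when leaving out an array, 0 without _x_at and _s_at probe sets, 6 without both arrays of highest ACTB ratio, and 0 with an estimated correlation or fry.

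For IGF1R against LPS, the count of 177 genes became 114 with quantile normalization, 89 with no filter, 289 with the filter at the 75th percentile, 0 with no trend or the ACTB covariate, 1 to 383 when leaving out an array, 64 with averaged probe sets, 107 without _x_at and _s_at probe sets, 2094 without both arrays of highest ACTB ratio and 11422 with poly-A scaling. The 11 lists became 4 with the ACTB covariate, 0 with an estimated correlation and 3 by fry, and were 8 to 12 when leaving out an array.

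The replicate number, which is also the fluidics run, left little shared deviation over all genes. Deviations from the group means correlated across genes at 0.0469, 0.00511 and -0.0202. With it as a replicate block, the counts were higher than without it, at 197, 47 and 281 genes in the 3 comparisons, and the lists were 11, 4 and 12. An effect of the run on some of the genes therefore stays open.

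The correlation of both sets of fold changes, 0.406, was 0.294 to 0.583 when leaving out an array, and 0.0964 and -0.0450 with a different control array for each treatment.

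With poly-A scaling, log2 fold changes turned in IGF1R against control for GADD45A (-0.48), E2F1 (-0.55), CHAF1A (-0.84), DDIT3 (-0.33), HSP90B1 (-0.45), NRIP1 (-0.0150), LYAR (-0.36), H2BC21 (-0.10) and the IGF1R probe sets 203627_at (-1.19), 203628_at (-0.88) and 225330_at (-1.08). In IGF1R against LPS this held for INSR (-0.30), EGR1 (-0.0669), DUSP6 (-0.18), ATF3 (-0.30), DUSP4 (-0.77), E2F1 (-0.96), RRM2 (-0.98), HLA-C (-1.20), CXCL8 (-0.63), PPP1R15A (-0.33), CD24 (-1.09), TWIST1 (-0.31), RPL3 (-0.98), RPL10A (-1.16), WDR43 (-1.13) and ODC1 (-1.15). The shift of all genes by construction turned these.

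With the ACTB covariate, ETV5 in LPS against control (0.36) and NDRG1 (0.0574), CYC1 (0.18) and WDR43 (-0.12) in IGF1R against LPS turned. RPS23 in LPS against control turned with averaged probe sets (0.0612). Ranges when leaving out an array, with the array at which the sign turned, were in IGF1R against control -3.05 to 0.54 for NDRG1 and -1.95 to 0.25 for ANKRD37 (control replicate 2), -1.29 to 0.14 for LY96 (IGF1R replicate 2), -0.0158 to 0.23 for 203627_at and -0.000412 to 0.42 for 225330_at (both IGF1R replicate 1). LY96 in LPS against control ranged from -0.0212 (control replicate 1) to 0.95. Without both arrays of highest ACTB ratio, LY96 in LPS against control (-0.0212), 203627_at (-0.0480) and 225330_at (-0.0935) turned.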

Other observations

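The genes in these paragraphs were chosen only after their values were seen. In the IGF1R-labelled arrays, the interferon genes IFNB1 (log2 fold change 1.79 against control, limma, adjusted p = 0.0104) and IFNL2 (2.83-fold, adjusted p = 0.0216) rose. Genes known to be inducible by interferon that fell were SAMHD1 (-1.24, adjusted p = 0.00865), DHX58 (-1.15, adjusted p = 0.0413), IFITM2 (-0.98, adjusted p = 0.0135), IFITM3 (-0.89, adjusted p = 0.0207) and TRIM22 (-0.73, adjusted p = 0.0189). The gene EDN1, which encodes the vasoconstrictor peptide endothelin, rose by 2.15 (adjusted p = 0.000367), and CYP1B1, which encodes a cytochrome P450 enzyme, by 1.45 (adjusted p = 0.00545). Another CYP1B1 probe set, not the one representing the gene, also rose in LPS against control (1.16, limma, adjusted p = 0.0452). The ribosomal RNA precursor gene RNA45SN5 rose by 1.95 (adjusted p = 0.0168). In the same arrays the middle 28S ribosomal RNA probe set was higher too, at 1276 against 271 in control. A rise of the precursor can therefore not be told apart from more ribosomal RNA signal in general.

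Of 7 measured genes encoded in the mitochondrial genome, 5 were higher in IGF1R-labelled than in LPS arrays in limma, and all 7 had a fold change above 0. The group was picked because its members were called. Among all genes, 177 were called in this comparison, but 0 with the ACTB 3'/5' ratio as a covariate, an alternative chosen after seeing the data, 3 without LPS replicate 1 and 1 without LPS replicate 2. The ACTB ratio largely follows the LPS group, so that covariate cannot tell RNA quality or labelling from treatment. Against control, 1 of the 7 rose.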
